A study of Mus musculus with 6 samples.

How the data were processed

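RNA of 6 mammary organoid cultures, 3 without doxycycline and 3 with it, was measured on 1-colour Affymetrix mouse whole-transcript arrays. The deposited values are log2 expression summaries per probe set, and the submitters' processing notes name RMA and the affy package without versions. The table was used as deposited. RMA usually includes a quantile normalization between arrays, and the quartiles of the deposited columns differed all the same: 4.10 to 4.29 and 7.34 to 7.46 in 5 arrays against 4.83 and 6.90 in DOX replicate 2. RMA gives no detection calls, so the difference of a gene that lies near the lower end of the scale in 1 group can be understated. No scan date or batch is given in the labels. Replicate numbers and groups were taken from the sample titles.

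Of 34760 probe sets, 21640 were assigned 1 gene symbol by the platform annotation, 1321 were assigned several and 11799 had no gene symbol here. The last 2 kinds, 37.7% of probe sets, stayed out of the gene analysis. Symbols were checked through gene identifiers against a mouse gene table of the GRCm38.p6 assembly, and 0 changed. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 19937 genes. Among 954 genes with 2 or more probe sets, 0 had probe sets called in opposite directions with all arrays and 11 without DOX replicate 2. No coordinates are given, because the build used for the array's annotation is not given in the sources used here.

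Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, two-sided), and p values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Differences are DOX minus control on the log2 scale, and standard errors are moderated. The 31 gene lists, with 592 genes of which 550 were measured, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. They covered ErbB receptors and ligands, luminal, hormone-sensing, luminal progenitor, milk, basal, mesenchymal and squamous genes, the cell cycle, signalling and stress pathways, metabolism, interferon and inflammation, extracellular matrix, and markers of other cell types. Within a list, genes were also adjusted over the list alone. Estimated correlation and fry were alternatives. The form of camera with an estimated correlation differs from the preset form in more than the correlation. The milk list's p rose with it although its estimated correlation, −0.0144, lay below 0.01. A call lost with it is therefore no measure of the correlation between genes alone. The mean luminal minus mean basal level per array and the Erbb3 level were compared with a two-sided exact permutation test.

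The genes named were chosen by a rule written before the data were examined: Erbb3, the 15 genes with the largest difference in each direction among genes past the threshold whose arrays did not overlap between groups and whose higher group mean lay above the median of all genes, 5.92, and up to 4 members of each list past the threshold, or else past it over the list alone, or else the 2 with the smallest p. Krt8, Krt18, Krt5, Krt14, Erbb2, Egfr, Erbb4, Nrg1, Csn2 and Wap were named whatever their p. Predicted genes without a name were skipped, and not every gene the rule picked is described. Genes chosen after their values were seen are marked as such.

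Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array, leaving out the 25% or the 50% of genes with the lowest means, a second quantile normalization, centring each array on its median, the mean over a gene's probe sets, a variance trend with robust estimation, array weights, probe sets one by one, each gene's own variance without sharing, other thresholds, and other set tests. Leaving out probe sets by their name ending did not apply, since this array's identifiers carry no such endings. Array weights were computed gene by gene, because the default estimate did not converge. Cyclic loess normalization between arrays, the lists without DOX replicate 2 at an estimated correlation, and the mixed form of fry were chosen after seeing the data. The planned check of RNA quality from 3' and 5' control probe sets was not run, since no probe set is named as such a control here.

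The gene and list tests were tested on simulated data with 19937 genes, the real arrays' means and spread, and 100 genes changed at each of 2 fold sizes. With all 6 arrays 2% of 2-fold and 43% of 4-fold changes were recovered, and 4.17% of the calls were unchanged genes. Without DOX replicate 2 the shares were 83% and 100%, with 2.83% of the calls unchanged genes. A list shifted by a known amount was called in both, and 0 unshifted lists were. The simulated genes varied independently of each other, with the same spread of a gene on every array. The list result is therefore no check of the preset correlation in the real arrays, where estimated correlations reached 0.96. Those estimates were made with all 6 arrays, DOX replicate 2 included, whose difference from the controls followed the expression level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.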

Results

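Gene expression was measured in mammary epithelial organoids, small clumps of gland tissue released by enzymes and grown in a basement-membrane gel. The organoids came from FVB-strain mice with an inducible knockout of Erbb3, which encodes a receptor of the epidermal growth factor receptor family that binds neuregulins. Cultures were kept for 14 days with 5 µM doxycycline (DOX), the drug that switches the knockout on, or without it. RNA of each culture was hybridised to 1 mouse whole-transcript array, giving 3 control arrays and 3 arrays labelled DOX. The series describes 3 biological replicates, and whether each came from a different mouse is not given in the labels. The number of arrays limits the precision of every value below. The comparison asks which genes differ between organoids induced to lose Erbb3 and uninduced organoids, and whether luminal and basal markers shift against each other.

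Erbb3 itself was not lower in the arrays labelled DOX. Its single probe set read 9.73 ± 0.05 on the log2 scale in control arrays (SD, n = 3) and 9.83 ± 0.53 in arrays labelled DOX (SD, n = 3). The control values were 9.78, 9.71 and 9.69, and DOX replicates 1, 2 and 3 read 10.36, 9.31 and 9.82. The difference of 0.10 (95% confidence interval −0.58 to 0.79, limma adjusted p = 0.845) was within the spread between arrays, and a two-sided exact permutation test gave p = 0.7, where 0.1 is the smallest p possible. Without DOX replicate 2 the difference was 0.37 (95% confidence interval 0.03 to 0.70). Its limma p was 0.0356 unadjusted and 0.105 adjusted over all genes, and the exact permutation p was 0.1, again the smallest possible. Without DOX replicate 1 the difference was −0.16. That value rests in part on DOX replicate 2, where genes in the 10% step nearest the control level of Erbb3 differed from control by a median of −1.59. A probe set of this array averages probes along the transcript, and the deleted exons are not given in the labels, so the value is no clean check of the labels. All directions below follow the arrays as labelled.

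Casein, cell cycle and interferon-induced genes fell in the arrays labelled DOX, and genes that include the stress regulators Ddit3 and Nupr1 rose. The balance of rises and falls depended on DOX replicate 2, with 5.06% of the calls higher with all arrays and 46.2% without it. Csn2, which encodes the milk protein beta-casein, went from 12.86 ± 0.04 in control arrays to 5.64 ± 0.53 in arrays labelled DOX (SD, n = 3 each), a log2 difference of −7.22 (SE 0.29, limma adjusted p = 8.70e-04). Ccna2, which encodes cyclin A2, and Top2a, a DNA topoisomerase of dividing cells, fell, with log2 differences of −4.02 and −4.01 (SE 0.29 and 0.25). The mean over both probe sets of Top2a gave −2.21 (limma adjusted p = 0.004). Irf7, a transcription factor of the interferon response, fell by 3.74 (SE 0.32). Ddit3, also known as Chop, rose by 2.44 (SE 0.16, limma adjusted p = 0.002).

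**Figure D1:**
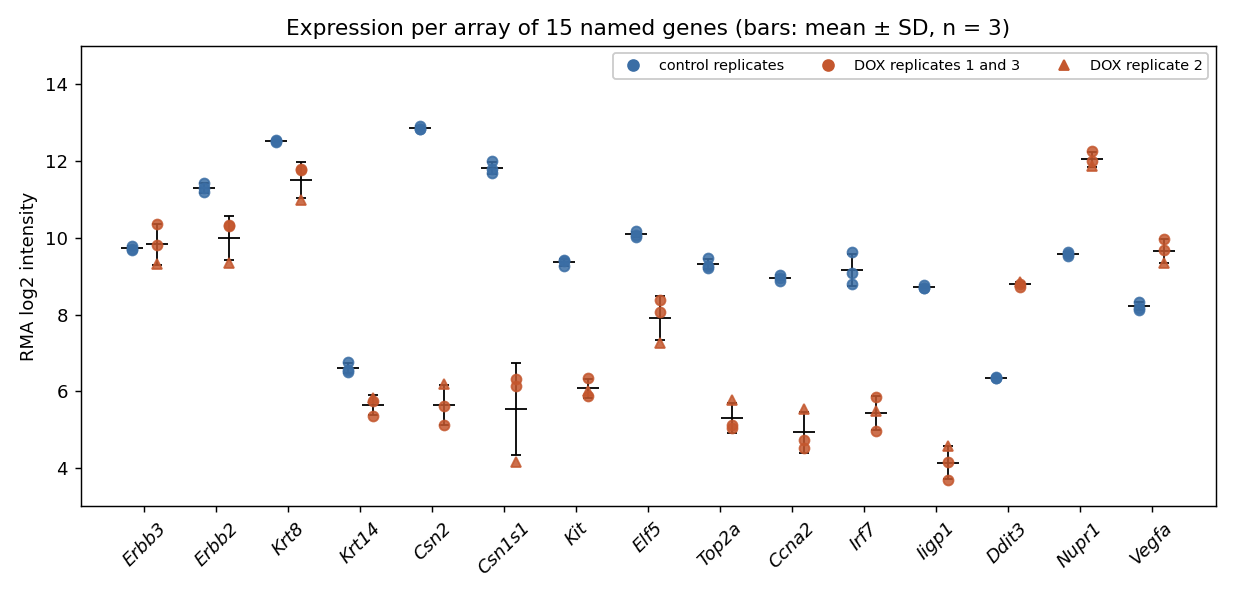
RMA log2 intensity (vertical axis) of 15 named genes on each array, with blue points for control arrays, orange circles for DOX replicates 1 and 3, an orange triangle for DOX replicate 2, and bars for the mean and SD of 3 arrays. Csn2 lies near 12.86 in the control arrays and near 5.64 in the arrays labelled DOX, while the Erbb3 values of the groups overlap.

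In all 6 arrays, 24 of 19937 genes were higher and 450 lower at an adjusted p under 0.05 in limma. All 24 and 436 of the 450 differed by at least 2-fold. The 3 arrays labelled DOX lay wholly above or wholly below the control arrays for all 474 of these genes and for 6384 genes in total, which is 32.0% of all genes against 10% by chance. DOX replicate 2 stood apart from the other arrays. Its correlation with any other array was 0.816 to 0.865 across genes, against at least 0.963 among the other 5, and its slope on the control mean was 0.548, against 0.981 and 0.936 for DOX replicates 1 and 3. Genes in the lowest 10% of control levels read a median of 0.84 higher on that array, and the median log2 difference of genes in the top 10% was −1.59. Without it, 2454 of the 19937 genes were higher and 2855 lower, among them all 24 and all 450 genes above. That fit rests on 2 arrays labelled DOX. Counts of list members or of other gene groups given below without DOX replicate 2 are to be read against these counts over all genes. The share of higher genes among the calls was 5.06% with all arrays and 46.2% without DOX replicate 2. A second quantile normalization between arrays moved that share to 22.9% (186 higher, 627 lower). Leaving out any other single array gave 2 to 9 higher and 61 to 264 lower genes, and 22 of 53 named genes called with all arrays kept their call without control replicate 1 or without control replicate 3.

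**Figure D2:**
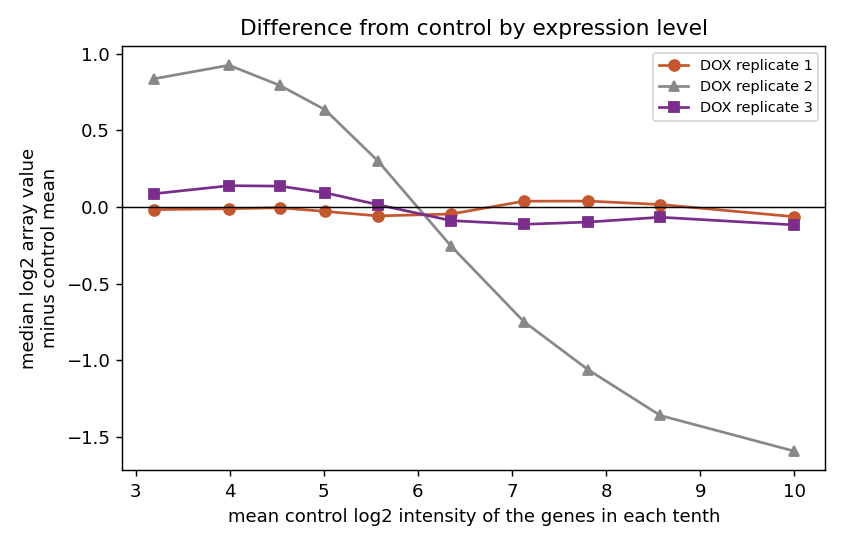
Median log2 value of each array labelled DOX minus the control mean (vertical axis) for genes ranked by mean control log2 intensity and grouped in steps of 10% (horizontal axis), with 1 line per array. The line of DOX replicate 2 runs from 0.84 in the lowest 10% to −1.59 in the top 10%, and the other arrays stay near 0.

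Milk genes gave the largest differences. Of 17 measured members of the milk production list, 8 fell, none rose and 9 did not pass, and 12 fell when adjusted over the list alone. The casein genes Csn1s2a (−7.63, SE 0.37), Csn1s1 (−6.28, SE 0.57) and Csn1s2b (−3.60, SE 0.24) all fell. Wap, which encodes whey acidic protein, differed by −0.46 (limma adjusted p = 0.482) with all arrays and by −0.79 (limma adjusted p = 9.09e-04) without DOX replicate 2. The list's median log2 difference was −2.61 (limma camera adjusted p = 3.88e-13). The call held with an estimated correlation (adjusted p = 0.0194) but not when DOX replicate 2 was left out as well (adjusted p = 0.121 with an estimated correlation). With all arrays the estimated correlation of this list was −0.0144, below the preset 0.01, so correlation does not account for the higher p. Without DOX replicate 2, 13 members fell and 1 rose.

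Genes of luminal progenitors, the immature cells of the inner epithelial layer, fell in part. Of 15 measured members 5 fell and none rose, and 7 fell when adjusted over the list alone. Decreases were seen for Kit, a receptor tyrosine kinase (−3.28, SE 0.20), Elf5, a transcription factor needed for alveolar development (−2.19, SE 0.31), Itgb3 (−2.39, SE 0.19) and Lbp (−4.65, SE 0.33). The median was −0.91 (limma camera adjusted p = 1.78e-05), and the call was lost with an estimated correlation (adjusted p = 0.331). In the 5 other arrays 9 members fell and 3 rose.

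With all arrays and genes, the balance of luminal against basal markers did not differ beyond the spread between arrays, and its direction changed between alternatives. Of 21 general luminal markers none passed over all genes, and 5 were lower and 1 higher when adjusted over the list alone. Without DOX replicate 2, 7 were lower and 3 higher over all genes. Krt8 and Krt18, keratins of luminal cells, differed by −1.01 and −0.64 (limma adjusted p = 0.145 and 0.135), and passed without DOX replicate 2 (−0.74 and −0.64, limma adjusted p = 4.94e-04 and 0.0016). Tfap2c differed by −1.66, Elf3 by −1.07 and the tight junction gene Cldn4 by 1.42 (limma adjusted p = 0.115, 0.0528 and 0.192). These genes also passed without DOX replicate 2 (−1.22, −0.92 and 1.88, limma adjusted p = 1.71e-04, 1.60e-04 and 1.01e-05). The luminal list's median of −0.64 passed (limma camera adjusted p = 0.0097) but not with an estimated correlation (adjusted p = 0.734), nor without DOX replicate 2 (median −0.14, limma camera adjusted p = 0.135). The list's median control level was 9.98. On DOX replicate 2 its median difference was −1.11, against −1.59 for all genes in the top 10% of control levels. Of 25 basal and myoepithelial genes, those of the outer contractile layer, 2 fell and none rose, and 3 fell when adjusted over the list alone. The 2 were Dll1, a Notch ligand (−2.86, SE 0.45), and Oxtr, the oxytocin receptor (−1.91, SE 0.26). Without DOX replicate 2, 5 basal genes fell and 1 rose. The basal keratins Krt5 and Krt14 differed by 0.07 and −0.96 (limma adjusted p = 0.886 and 0.0831). The basal list did not pass (limma camera adjusted p = 0.955), and its median of 0.07 was positive while its mean of −0.17 and its test pointed down. With the 50% of genes with the lowest means left out, which kept 7 of the 25, its median was −1.02 and it passed as lower (limma camera adjusted p = 0.0322). The mean luminal minus mean basal level was 3.11 ± 0.04 in control arrays and 2.80 ± 0.61 in arrays labelled DOX (SD, n = 3 each). This difference of −0.31 had p = 0.7 in a two-sided exact permutation test, whose smallest p is 0.1, and the difference was 0.034 without DOX replicate 2. With the 50% of genes with the lowest means left out it was 0.67 (exact permutation p = 0.1), and without DOX replicate 1 it was −0.54. Of 11 hormone-sensing luminal genes none passed (median 0.02, mean −0.01, limma camera adjusted p = 0.614).

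Cell cycle genes fell together. Of 29 measured members 23 fell and none rose, 28 fell when adjusted over the list alone, and 29 fell without DOX replicate 2. Plk1, a mitotic kinase (−3.50, SE 0.17), and Kif20a, a mitotic kinesin (−3.44, SE 0.19), were among them. The median was −2.36 (limma camera adjusted p = 5.26e-37), and the call held with an estimated correlation both with all arrays (adjusted p = 0.0194) and without DOX replicate 2 (adjusted p = 0.026).

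Interferon response genes also fell. Of 20 measured members 13 fell and none rose, 17 fell when adjusted over the list alone, and 18 fell without DOX replicate 2. Ifit3 (−2.92, SE 0.24), Oasl2 (−2.63, SE 0.27) and Ifit1 (−2.61, SE 0.35) were among them. Iigp1, an interferon-inducible GTPase outside the list, fell by 4.59 (SE 0.25). The median was −1.57 (limma camera adjusted p = 3.15e-16), and the call was lost with an estimated correlation (adjusted p = 0.149). Of 21 inflammatory cytokine and acute phase genes none passed over all genes, and Csf3 (−1.57, limma adjusted p = 0.0754) alone passed when adjusted over the list alone. That list did not pass as a set (limma camera adjusted p = 0.614), and without DOX replicate 2, 5 of its members rose and 4 fell.

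Of 20 cholesterol synthesis genes 5 fell and none rose, and 16 fell when adjusted over the list alone. Tm7sf2 (−1.86, SE 0.28), Pmvk (−1.63, SE 0.17), Stard4, a sterol carrier (−1.62, SE 0.20), and Mvd (−1.46, SE 0.20) were among those that passed over all genes. The median was −1.35 (limma camera adjusted p = 3.88e-13), and the call was lost with an estimated correlation (adjusted p = 0.415). No single member of the fatty acid synthesis (16 genes), nuclear-encoded oxidative phosphorylation (26 genes) or mitochondrial ribosome (23 genes) lists passed over all genes, although each list lay lower as a set. Their medians were −1.09, −0.78 and −0.53 (limma camera adjusted p = 1.68e-05, 1.10e-06 and 9.81e-04). All 3 calls were lost with an estimated correlation (adjusted p = 0.734 each). Srebf1, a regulator of lipid synthesis, differed by −2.26 (limma adjusted p = 0.0509) and was the only member of these lists to pass when adjusted over its list alone. On DOX replicate 2 the medians of the 3 lists lay at −2.03, −1.61 and −1.06 from the control mean. Genes in the 10% steps nearest their control levels read −1.59, −1.59 and −1.06 there. On that array the last 2 lists thus moved about as other genes of their level did. Without DOX replicate 2 the medians of the 3 lists were −0.70, −0.45 and −0.20. In the 5 other arrays 11, 16 and 5 members of the 3 lists fell and 0, 0 and 1 rose. Of 21 glycolysis and hypoxia genes, Aldoc, an aldolase (−3.59), and Egln3 (−3.07) fell, Vegfa rose by 1.45, and the list did not pass (limma camera adjusted p = 0.186).

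Among ErbB receptors and ligands, 1 of 15 genes fell and none rose, and 2 fell when adjusted over the list alone. Nrg2, a neuregulin gene, fell by 1.34 (SE 0.23, limma adjusted p = 0.0407), and kept its call in 7 of 15 alternatives (highest adjusted p 0.25). Erbb2, the usual signalling partner of Erbb3, differed by −1.31 (limma adjusted p = 0.108) and by −0.98 without DOX replicate 2 (limma adjusted p = 1.33e-04). Egfr, Erbb4 and Nrg1 differed by −0.04, 0.31 and −0.15 (limma adjusted p = 0.94, 0.608 and 0.706), and the list did not pass (limma camera adjusted p = 0.614). Of 17 genes of ERK feedback and targets, Spry4, a feedback inhibitor, fell by 1.12 (SE 0.18). That list's median was −0.76 (limma camera adjusted p = 5.79e-04), and the call was lost with an estimated correlation (adjusted p = 0.734). In the 5 other arrays 9 of its members fell and 4 rose (median −0.43, limma camera adjusted p = 0.0344). On DOX replicate 2 the ERK median was −1.42, and genes in the 10% steps nearest its control level of 9.28 read −1.36 and −1.59. Of 17 FOXO targets none passed with all arrays (median −0.05, mean 0.09, limma camera adjusted p = 0.614). In the 5 other arrays 8 FOXO targets rose and 2 fell (median 0.30, limma camera adjusted p = 0.0218, adjusted p = 0.579 with an estimated correlation). Of 15 p53 targets, Gtse1, which is also a cell cycle gene, fell by 0.94 (median −0.07, limma camera adjusted p = 0.987). In the same arrays the p53 list had a median of 0.30 (limma camera adjusted p = 0.0347, adjusted p = 0.579 with an estimated correlation), with 4 members higher and 1 lower. No member of the PI3K and AKT pathway (16 genes) or apoptosis (18 genes) lists passed over all genes, and Pik3r3 (−2.26, limma adjusted p = 0.0829) passed when adjusted over the first list alone. Without DOX replicate 2, 5 PI3K genes rose and 3 fell, and 2 apoptosis genes rose and 3 fell. Sfrp1, a Wnt antagonist, fell by 1.65 among 19 Wnt genes, and Dll1 was the only one of 13 Notch genes to pass over all genes. When adjusted over the list alone, 3 Wnt genes and 4 Notch genes fell. Without DOX replicate 2, 3 Wnt genes fell and 1 rose, and 5 Notch genes fell and 4 rose. That fit called 5309 of all 19937 genes, so a few called members do not by themselves set a list apart. The limma camera adjusted p was 0.155 for the PI3K list, 0.19 for the apoptosis list, 0.19 for the Wnt list and 0.252 for the Notch list.

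The genes that rose included Nupr1 by 2.47 (SE 0.18, from 9.58 to 12.04), Niban1 by 2.78 (SE 0.49), Bpifc by 2.68 (SE 0.36), Stbd1 by 1.96 (SE 0.31), Maoa, which encodes monoamine oxidase A, by 1.84 (SE 0.33), the long noncoding RNA Malat1 by 1.61 (SE 0.25), the angiogenic factor gene Vegfa (SE 0.22) and Ahnak by 1.37 (SE 0.18). Nupr1 and Ddit3 kept their calls in all 15 alternatives, Bpifc and Stbd1 in 10, Niban1 and Malat1 in 8, and Maoa, Vegfa and Ahnak in 7 (highest adjusted p of these 7 genes 0.133 to 0.261). Of 20 genes of the ATF4 amino acid response, Ddit3 rose and no other passed over all genes. When adjusted over the list alone 4 were higher and 2 lower. That list did not pass (limma camera adjusted p = 0.581), and its median of −0.06 was negative while its mean of 0.10 and its test pointed up. It passed in the mixed form of fry, which counts changes in both directions (adjusted p = 2.23e-05). In the 5 other arrays 8 of its members rose and 5 fell (median 0.25, limma camera adjusted p = 0.0506). Of 19 heat shock and unfolded protein response genes none passed (limma camera adjusted p = 0.579), and without DOX replicate 2, 8 rose and 3 fell.

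Other large decreases were those of Apod, which encodes a lipid-binding protein (−5.10, SE 0.40), Atp6v1b1, a proton pump subunit (−4.87, SE 0.25), Igfbp5, an insulin-like growth factor binding protein (−4.78, SE 0.17), and Gabrp (−4.61, SE 0.64). Cnmd (−4.56, SE 0.32), the fatty acid transporter gene Cd36 (−4.27, SE 0.25) and Cnp (−3.61, SE 0.40) also fell. In the mesenchymal transition list (20 genes) Fn1, which encodes fibronectin, rose by 1.22 (SE 0.16), and in the extracellular matrix list (24 genes) Tnc, tenascin C, fell by 2.54 (SE 0.24). Neither list passed (limma camera adjusted p = 0.254 and 0.19), nor did that of squamous keratinization (16 genes, limma camera adjusted p = 0.19).

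Markers of other cell types moved mainly with DOX replicate 2. No member of the fibroblast (15), adipocyte (12), endothelial (15), macrophage and myeloid (18) or lymphocyte (14) lists passed over all genes. On DOX replicate 2 the list medians lay 0.75, 0.47, 0.67, 0.70 and 0.85 above the control mean. On DOX replicate 1 they were −0.15, 0.06, −0.01, −0.10 and −0.01, and on DOX replicate 3 they were 0.09, 0.08, 0.06, 0.09 and 0.22. The lymphocyte list passed as a set (median 0.42, limma camera adjusted p = 0.0063) but not with an estimated correlation (adjusted p = 0.734), nor without DOX replicate 2 (limma camera adjusted p = 0.278). The other 4 lists had limma camera adjusted p = 0.0599, 0.178, 0.0843 and 0.178.

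In total 10 of the 31 lists were lower, 1 was higher and 20 passed in neither direction with the preset correlation, and 2 passed with an estimated correlation. The other splits of the 6 arrays into 3 and 3 gave 12 to 17 lists with the preset correlation and 0 genes. Each of them sets arrays of both groups on both sides. Part of the group difference stays between the sides, and the rest adds to the spread within them. Their counts therefore do not show what arrays without a group difference would give, for lists or for genes.

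**Figure D3:**
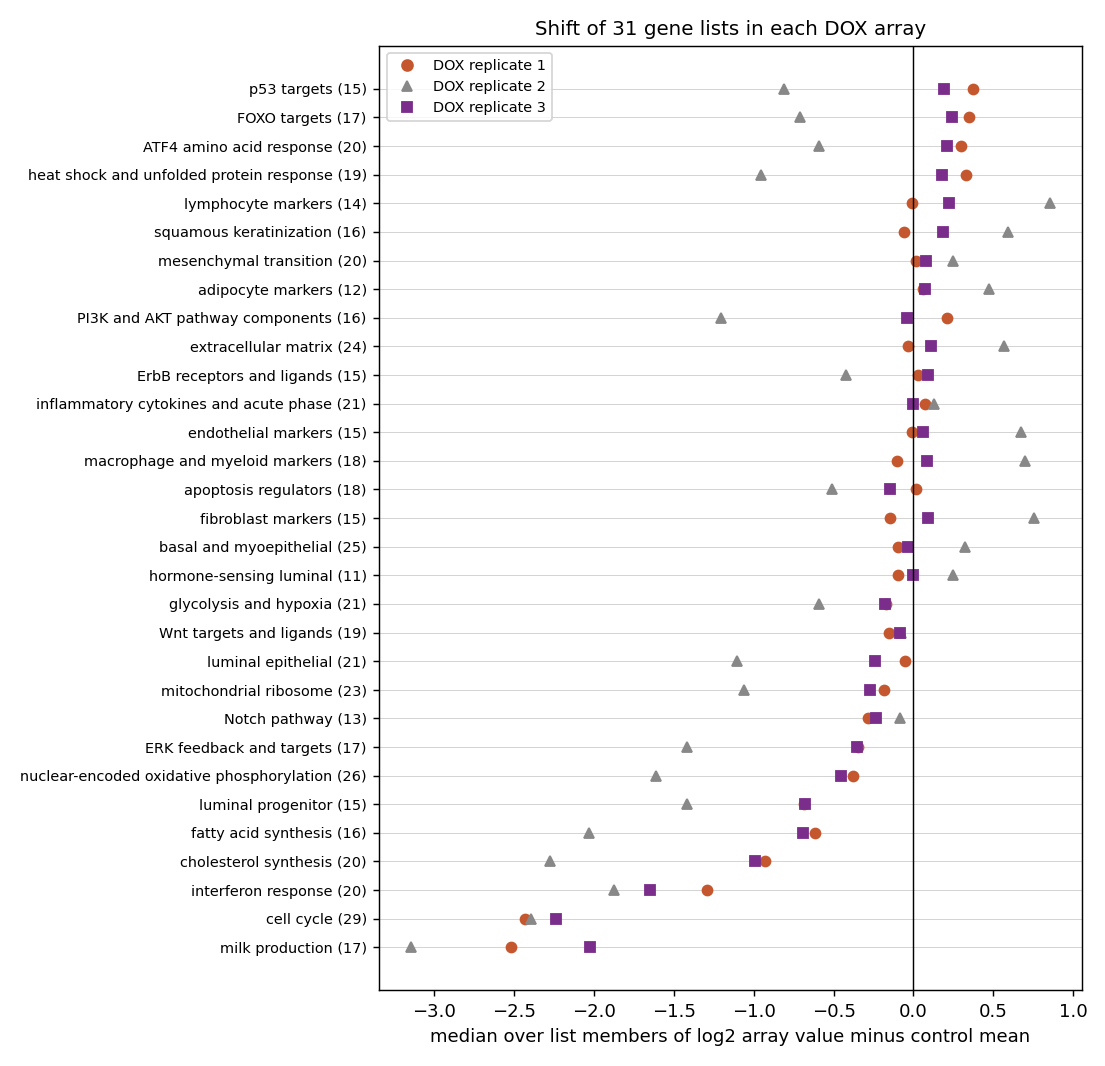
Median over the measured members of each of 31 gene lists (number of members in brackets) of the log2 value on each array labelled DOX minus the control mean. Milk production, cell cycle and interferon response lie below −1 on all 3 arrays, and the luminal epithelial list is at −0.05 and −0.24 on DOX replicates 1 and 3 and at −1.11 on DOX replicate 2.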

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

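All tests of explanations in this part were chosen after the results were seen. Probe sets left out of the gene analysis also differed between the groups. Of 11799 probe sets with no gene symbol here, 13 were higher and 12 lower in the arrays labelled DOX (limma adjusted p under 0.05 over these probe sets), and 386 were higher and 107 lower without DOX replicate 2. Of 1321 probe sets with several gene symbols, 0 were higher and 24 lower with all arrays (limma), and 159 were higher and 116 lower without DOX replicate 2.

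DOX replicate 2 stood apart from the other 5 arrays. A stronger form of the response of DOX replicates 1 and 3 is argued against as the whole cause, since 5809 genes that lay within 0.2 of the control mean on both of those arrays differed by a median of 0.69 (absolute log2 difference) on DOX replicate 2, against at most 0.103 on a control array. A compressed signal on this array goes with the slope of 0.614 (SE 0.0042) of its values on the control mean over the same genes, where control arrays had slopes of 0.985 to 1.01. Its correlations with the other arrays, 0.816 to 0.865, were also low, which an even compression alone would not give. Weak labelling, degraded RNA or another treatment of the array could not be separated. RNA of fibroblasts, adipocytes, endothelial or immune cells stays open in small amounts: the median difference of their 74 markers, 0.75, lay at the 81.4th percentile of 10000 lists matched on control level, within their 95% range of 0.47 to 0.85, but of the 5 markers above the 75th percentile of levels on that array 4 lay higher than in the controls, Ighm (7.50, against 4.96), Col1a2 (7.18, against 6.00), Col1a1 (7.08, against 6.46) and Cd3e (7.06, against 5.64), while Pnpla2 lay lower (7.69, against 9.28). A biological difference of that culture was not tested.

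Erbb3 was not lower in the arrays labelled DOX. An exchange of single arrays between the groups is argued against, since the highest correlation of a control array with DOX replicate 1 or 3 across genes was 0.968, below the lowest within the controls (0.995) and that of DOX replicates 1 and 3 with each other (0.992). A probe set that reads parts of the transcript outside the deleted exons may account for the difference of 0.10 with all arrays, and a persistence of Erbb3 in these cultures may account equally for it and for the 0.37 without DOX replicate 2. These cannot be told apart, because no probe-level values were analysed here and the deleted exons are not given in the labels. An exchange of all labels between the groups is not excluded by any value here.

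Milk, cell cycle and interferon genes were lower in the arrays labelled DOX. A compressed signal on DOX replicate 2 is argued against as the cause, since without that array the list medians were −2.26, −2.16 and −1.48. A lower share of luminal against basal cells cannot be decided by the luminal minus basal difference, because most basal members read low. Their median control level was 5.25, and 7 of 25 lay above the median of all genes, 5.92. The difference was 0.034 without DOX replicate 2. DOX replicates 1 and 3 read 3.25 and 3.03, against 3.08 to 3.15 in the controls. With the genes with the lowest means left out, which kept 7 of the 25, the difference was 0.665 with all arrays. Its exact permutation p was 0.1, the smallest possible. A loss of milk-producing cells alone stays open as well. Loss of Erbb3 and doxycycline acting by itself cannot be told apart, because no organoids without the inducible knockout received the drug here. The ATF4 list, which responds to disturbed mitochondrial translation among other stresses, had a median of −0.06 with all arrays and of 0.25 without DOX replicate 2. It passed in neither (limma camera adjusted p = 0.581 and 0.0506, the second 0.579 with an estimated correlation). The mixed form of fry, which counts changes in both directions, called it with all arrays (adjusted p = 2.23e-05). Without DOX replicate 2 the oxidative phosphorylation and mitochondrial ribosome lists were lower (limma camera adjusted p = 3.91e-05 and 0.0344, or 0.307 and 0.579 with an estimated correlation). The real split was the 1 of the 10 splits of the 6 arrays with as many genes (474 genes, highest other split 0), and all 10 of the 10 splits gave at least as many lists as the real one (11 lists, highest other split 17). With 10 splits no share under 0.05 can be reached. Every other split of the 6 arrays sets arrays of both groups on both sides. None is free of the group difference, so they do not show what chance gives, for genes or for lists. Why other splits gave as many lists was not tested. The part of the group difference they keep, another structure of the arrays and a preset correlation of 0.01 that is too low all stay open. Estimated correlations reached 0.96, but they come from the spread within groups, which DOX replicate 2 dominates. Without DOX replicate 2 the real split gave 5309 genes and 11 lists, and the highest of the other 9 splits gave 0 genes and 8 lists. These other splits also mix the groups on at least 1 side.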

How the results depend on the processing

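Cyclic loess normalization, the estimated correlation without DOX replicate 2 and the mixed form of fry were chosen after seeing the data, the other alternatives before. No named gene, list or value reversed after being called in an alternative that tested it; the other called genes were not followed one by one. The main counts were 24 higher and 450 lower genes and 11 of 31 lists. In the replicate block fit 3 genes were higher and 159 lower. Deviations of same-numbered arrays from their group means correlated at 0.117, 0.194 and 0.0852 across genes, and control replicate 3 gave 0.0877 with DOX replicate 1. DOX replicate 2 dominates the deviations in its group, so DOX replicates 1 and 3 gave nearly the same values with each control (−0.185 and −0.182 with control replicate 2). Whether the numbers pair the arrays could therefore not be decided. The block changed no list call. Leaving out 1 array gave 2 (without a control replicate) to 2454 (without DOX replicate 2) higher genes and 61 (without control replicate 3) to 2855 (without DOX replicate 2) lower genes. Other settings gave 186 higher genes (second quantile normalization), 7 higher (arrays centred on their medians), 3643 higher and 3752 lower (array weights, with DOX replicate 2 at a weight of 0.0333), 557 higher and 1197 lower (cyclic loess), 15 higher and 267 lower (each gene's own variance), 73 higher (adjusted p under 0.1), 630 higher and 2165 lower (unadjusted p under 0.05), and 144 higher and 1004 lower (unadjusted p under 0.01). The share of higher genes was 22.9% after a second quantile normalization and 31.8% after cyclic loess, against 5.06%. The median log2 difference of all genes was 0.02 as deposited, −0.09 after the second quantile normalization and −0.18 after centring. The Erbb3 difference ranged from −0.16 to 0.51 and never passed over all genes (limma adjusted p = 0.105 to 0.932). The luminal minus basal difference ranged from −0.54 without DOX replicate 1 to 0.67 without the 50% of genes with the lowest means. The cell cycle list passed in every alternative (adjusted p 2.20e-40 to 0.026). The milk list passed in all but 1 (8.63e-17 to 0.121), and the interferon, cholesterol and luminal progenitor lists in all but 2 (highest adjusted p 0.307, 0.415 and 0.331). An estimated correlation left 2 lists (adjusted p 0.149 for interferon, median −1.57; 0.415 for cholesterol, −1.35; 0.331 for luminal progenitor, −0.91; 0.734 for luminal epithelial, −0.64, ERK, −0.76, oxidative phosphorylation, −0.78, mitochondrial ribosome, −0.53, fatty acid, −1.09, and lymphocyte, 0.42). Leaving out DOX replicate 2 as well left 1 list and ended the calls of milk (median −2.26), luminal epithelial (−0.14), luminal progenitor (−0.66), ERK (−0.43), oxidative phosphorylation (−0.45), mitochondrial ribosome (−0.20), cholesterol (−0.96), fatty acid (−0.70), interferon (−1.48) and lymphocyte (0.12). Directional fry gave 7 lists, ending those of luminal epithelial, ERK, oxidative phosphorylation, mitochondrial ribosome, fatty acid and lymphocyte genes and adding mesenchymal transition (0.085) and Wnt (−0.20), and mixed fry gave 13. Without the 25% of genes with the lowest means the luminal list no longer passed (−0.68), and squamous (0.38) and fibroblast (0.27) lists did. Without the lowest 50% the luminal (−0.73), ERK (−0.76) and mitochondrial ribosome (−0.53) lists no longer passed, and the basal list (−1.02) passed as lower and the extracellular matrix (0.15), FOXO (−0.051) and ATF4 (−0.14) lists as higher, the last 2 against the sign of their medians. The lymphocyte list, called with all genes, was not tested there, nor were the squamous, adipocyte, endothelial and myeloid lists, since fewer than 3 of their members were left. A second quantile normalization ended the mitochondrial ribosome (−0.41) and lymphocyte (0.20) calls and added extracellular matrix (0.25). Array weights ended the luminal (−0.27) and lymphocyte (0.21) calls and added FOXO targets (0.23). Cyclic loess ended luminal (−0.34), mitochondrial ribosome (−0.24) and lymphocyte (0.17). Leaving out 1 array moved the luminal median over −0.75 to −0.14, FOXO over −0.17 to 0.30, PI3K over −0.66 to 0.051, p53 over −0.23 to 0.30, fibroblast over −0.056 to 0.43, endothelial over 0.027 to 0.37, myeloid over −0.018 to 0.34 and lymphocyte over 0.12 to 0.62, each between leaving out DOX replicate 2 and DOX replicate 1. Without DOX replicate 1, 15 lists passed, adding PI3K as lower (adjusted p 0.0182) and fibroblast, endothelial and myeloid as higher (0.0042, 0.0244 and 0.0413). Without DOX replicate 3, 14 passed, adding PI3K as lower (0.0497) and fibroblast and endothelial as higher (0.0412 each). Without DOX replicate 2, 11 passed, with FOXO and p53 added as higher (0.0218 and 0.0347) and luminal epithelial and lymphocyte lost. The cause of these changes was not tested, except that fewer genes or arrays were tested where some were left out and that array weights nearly remove DOX replicate 2. On DOX replicate 2 the PI3K median was −1.20, and genes in the 10% steps nearest its control level of 8.30 read −1.06 and −1.36. Of 53 named genes called with all arrays, 53 kept their call without DOX replicate 2 and 22 without control replicate 1 or 3. Among the genes the report gives as fallen, the calls that did not hold in all held in 13 of 15 alternatives for Tnc, 12 for Aldoc, Cnp and Oasl2, 11 for Gabrp, Ifit1 and Pmvk, 10 for Elf5, Mvd, Oxtr, Sfrp1 and Stard4, 9 for Dll1, Gtse1 and Spry4, and 7 for Tm7sf2 and Nrg2. The call of Fn1 as higher held in 8 of 14, and the Top2a difference was −2.21 over the mean of its probe sets. RMA values carry no background measure, so the limit that signal over background sets is unknown.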

Other observations

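Genes in this part were chosen after their values were seen. Among the genes that fell in the arrays labelled DOX were 5 with roles in acid-base transport, picked singly and not tested as a set. Foxi1, a transcription factor of proton-secreting cells in kidney and inner ear, read 10.45 ± 0.07 in control arrays (SD, n = 3) and 7.05, 6.41 and 7.91 in DOX replicates 1, 2 and 3, a difference of −3.33 (SE 0.38, limma adjusted p = 0.0093). The proton pump subunit genes Atp6v1b1 and Atp6v1c2 (−4.87 and −3.26, SE 0.25 and 0.24) and the carbonic anhydrase genes Car2 and Car6 (−3.35 and −2.61, SE 0.49 and 0.37) also fell. All 5 also passed without DOX replicate 2, after a second quantile normalization, after centring of the arrays and after cyclic loess normalization. Of 21 measured subunit genes of the same proton pump only these 2 passed with all arrays, and without DOX replicate 2, 3 fell and 4 rose. Slc4a9 and Slc26a4, transporters of some proton- or bicarbonate-secreting cells, read 4.96 and 3.98 in control arrays and did not pass (limma adjusted p = 0.557 and 0.569).

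Col9a1 and Cnmd, which encode matrix proteins known from cartilage, and Matn2, another matrix gene, fell (−3.29, −4.56 and −3.33, SE 0.39, 0.32 and 0.38). The cartilage genes Acan and Col2a1 read 4.77 and 6.72 in control arrays and did not pass (limma adjusted p = 0.678 and 0.616). Of 30 measured linker and core histone genes, which were not tested as a set, 7 fell and none rose with all arrays, and 16 fell and 3 rose without DOX replicate 2. H1f5 fell by 3.32 (SE 0.20), while H1f2 differed by 1.66 with all arrays (limma adjusted p = 0.216) and by 2.27 without DOX replicate 2 (limma adjusted p = 1.53e-06). With all arrays H1f2 also passed after a second quantile normalization and after cyclic loess (limma adjusted p = 0.0311 and 0.0021), but not after centring (0.365).

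Several stress genes did not pass with all arrays as deposited, and passed without DOX replicate 2. Slc7a11, a cystine transporter gene, read 5.39 ± 0.18 in control arrays (SD, n = 3) and 10.11, 6.97 and 8.73 in DOX replicates 1, 2 and 3, a difference of 3.21 with all arrays (limma adjusted p = 0.0997) and 4.03 without DOX replicate 2 (limma adjusted p = 3.59e-06). Gadd45a, Trib3, Ppp1r15a, Hmox1 and Atf3 were higher than every control array on all 3 arrays labelled DOX, by means of 1.81, 1.40, 1.67, 1.05 and 1.45, and none of these passed with all arrays as deposited. In the 5 other arrays they were higher by 2.30, 1.79, 1.93, 1.48 and 1.42, and each passed (limma adjusted p at most 0.0041). With all arrays, Slc7a11, Gadd45a, Trib3, Ppp1r15a and Hmox1 passed after a second quantile normalization (limma adjusted p = 0.0459, 0.0081, 0.0135, 0.0087 and 0.0126) and Atf3 did not (0.0803), all 6 passed after cyclic loess (at most 0.0406), and none passed after centring of the arrays (at least 0.202). Of 6 small nucleolar RNA host genes measured, none passed with all arrays, and 4 rose without DOX replicate 2, among them Gas5 by 1.43 and Snhg5 by 1.24.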
